A study of Sus scrofa with 96 samples.

How the data were processed

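RNA was measured in 96 libraries from the jejunum mucosa, kidney cortex, liver and longissimus dorsi muscle of pigs (Sus scrofa). The series describes 24 animals, and each of the 8 groups of tissue and diet holds 12 samples. Libraries were made with QuantSeq, a 3' mRNA method in which each fragment comes from the end of a polyadenylated transcript, per the labels' protocols. Counts from such libraries need no correction for transcript length, and a gene whose 3' end is annotated wrongly can be missed.

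The deposited files hold raw counts per gene, 1 file per library, for 25880 Ensembl gene identifiers. STAR and featureCounts are named in the submitters' processing notes, without versions or roles, while the deposited files' names carry the name of another counter, HTSeq. The genome build, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Counts of paralogous, overlapping or antisense genes are therefore uncertain, and no gene coordinates are printed. Symbols came from a table that pairs 14857 of the 25880 identifiers with a symbol, and other genes are given by identifier. No molecular identifiers are described, so counts are of reads.

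Each file name holds the title of exactly 1 sample, and for 90 of the 96 files this is another sample than the one under which the file is recorded. Every comparison was therefore made under 2 assignments fixed before the data were examined. In the first, called recorded, each file belongs to the sample that the GEO record gives. In the second, called by title, each file belongs to the sample whose title is in its name. The diet and tissue of each sample come from the labels in either case. Under the record, every control library was in lane 7 (plate rows A to D) and every xylose library in lane 8 (rows E to H), so that diet, lane and row cannot be told apart and no lane term could be fitted. By title, each lane holds 6 control and 6 xylose libraries of each tissue, and lane was a term in the model. Tissue was checked with 4 lists of 20 marker genes. Of these, 19 (liver), 17 (jejunum), 16 (kidney) and 14 (muscle) had their symbol among the counted genes and were scored. A list's score was its mean log2(CPM + 1) minus its median over the 96 libraries, and an assignment was called contradicted when over 5% of its libraries scored highest on another tissue's list.

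Diet was tested per tissue with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values for genes come from this test unless another tool is named. A difference in diet effect between tissues was tested as the 3 interaction terms of a model over all 96 libraries. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, for lists with 5 or more tested members, adjusted over the lists of a tissue. The 41 lists (tissue and cell type markers and pathways) were also fixed before the data were examined. Levels are CPM, the count of a gene scaled to a library total of 1000000, with the total taken over tested genes and multiplied by the TMM factor for levels by diet, and taken over all genes as it is for levels by tissue and in the figure of single genes. They are given as mean ± SD over libraries, and errors of log2 fold changes are standard errors (SE). Fold changes are xylose against control.

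Genes were named by a rule fixed in advance. DCXR, SORD, AKR1B1 and XYLB were always named where tested. Of the genes past the threshold with a symbol and a mean of 1 CPM or more in either diet group, up to 10 in each direction with the smallest p were eligible, or 3 under a contradicted assignment, with up to 3 members of each list. Where no gene passed, the 3 genes with the smallest unadjusted p in each direction were named. Members of gene lists that did not pass, and the genes behind counts of 5 or fewer, were chosen after their values were seen. Some genes, among them named ones, are not reported here.

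Alternatives were DESeq2 size factors, no filter on low counts, a filter of 1 CPM in 12 libraries, the older edgeR fit, limma with library weights, DESeq2 1.42.0 as the test, no lane term, each lane alone, an estimated correlation for gene lists, a replicate block and the other assignment. Fits without libraries under 1000000 counts, or without a muscle library with liver transcripts, were added after the data were seen. Elsewhere no libraries were left out of a fit, except in random removals. Levels by tissue, the figure of single genes and the fractions of other tissues' markers left out libraries under 1000000 counts. All 276 pairs of libraries within a tissue were compared by chi-square over genes, and none were identical or agreed within sampling noise (smallest chi-square per degree of freedom 2.33).

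The edgeR step was tested on simulated data with 200 changed genes per run and 3 runs per tissue, drawn from the means, dispersions and library sizes of the by-title comparison. Of genes changed 2-fold, it recovered 60.2% in jejunum (8425 genes tested), 61.7% in kidney (10084 genes), 80.6% in liver (9035 genes) and 80.1% in muscle (8407 genes). Of genes changed 1.5-fold, it recovered 10.9%, 17.9%, 21.4% and 26.9% in the same order. False calls made up 3.8%, 5.1%, 3.2% and 5.4% of all calls. Genes were drawn independently, so neither a lane effect nor correlation between genes was simulated. Runs with fewer than 200 changed genes, where recovery could be lower, were not made.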

Results

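The study asked how D-xylose, a pentose sugar, alters gene expression in pig tissues that take up or metabolise it. Pigs received a semi-purified diet free of xylose or containing 8% xylose, and RNA was counted in jejunum mucosa, kidney cortex, liver and longissimus dorsi muscle, with 12 samples per tissue and diet. Library totals ran from 13418 to 6942566 counts with a median of 3393514. The 6 libraries under 1000000 counts were 5 with jejunum transcripts and 1 with liver transcripts, the latter holding the 13418 counts.

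**Figure D1:**
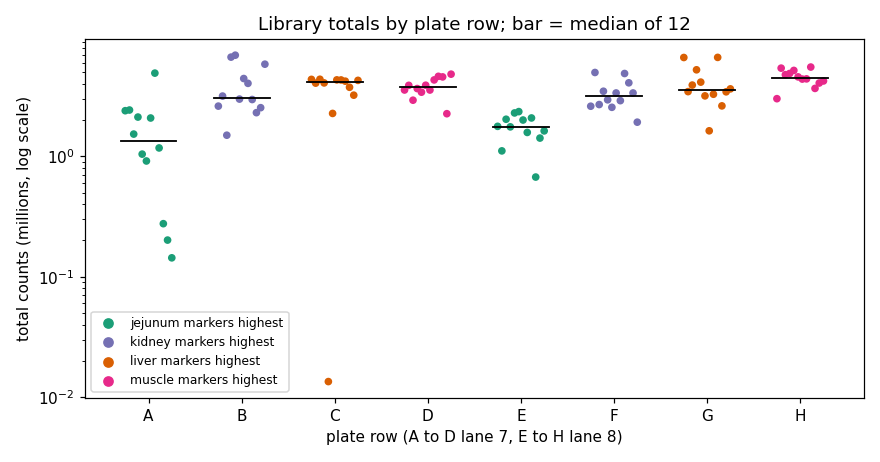
Total counts per library (log scale) by plate row, each point a library coloured by the tissue whose markers scored highest, with bars at the median of 12 libraries. Row A, with jejunum transcripts, has the lowest median (1354203 counts), and the lowest point is a row C library with liver transcripts at 13418 counts.

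Liver, jejunum, kidney and muscle transcripts separated the 96 libraries without overlap, but not along the tissues that the record gives. All 24 libraries recorded as jejunum carried liver transcripts, and all 24 recorded as liver carried jejunum transcripts. Albumin (ALB, ENSSSCG00000008948), the main plasma protein made by hepatocytes, stood at 119705 ± 52785 CPM in libraries recorded as jejunum and at 1774 ± 1316 CPM in those recorded as liver (SD, n = 24 each). FABP2, an enterocyte fatty acid binding protein, stood at 18.5 ± 43.8 CPM in the former and 3382 ± 2022 CPM in the latter. Kidney and muscle libraries carried the markers of their tissue under the record. The record thus matched the markers in 48 of 96 libraries, and the titles in the file names matched them in 96 of 96. The smallest gap between a library's highest and next marker score was 2.34 on the log2 scale. By the rule set in advance, the record was contradicted for tissue, with 50.0% of libraries not matching. In every plate row the recorded replicate number equalled the plate column. Tissue markers say nothing about diet, and the 2 assignments gave the same diet to 48 of 96 libraries. The recorded diets rest on the same link as the recorded tissues and are in doubt with them. No value was used to decide which diet a library had, and results are given under each assignment.

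**Figure D2:**
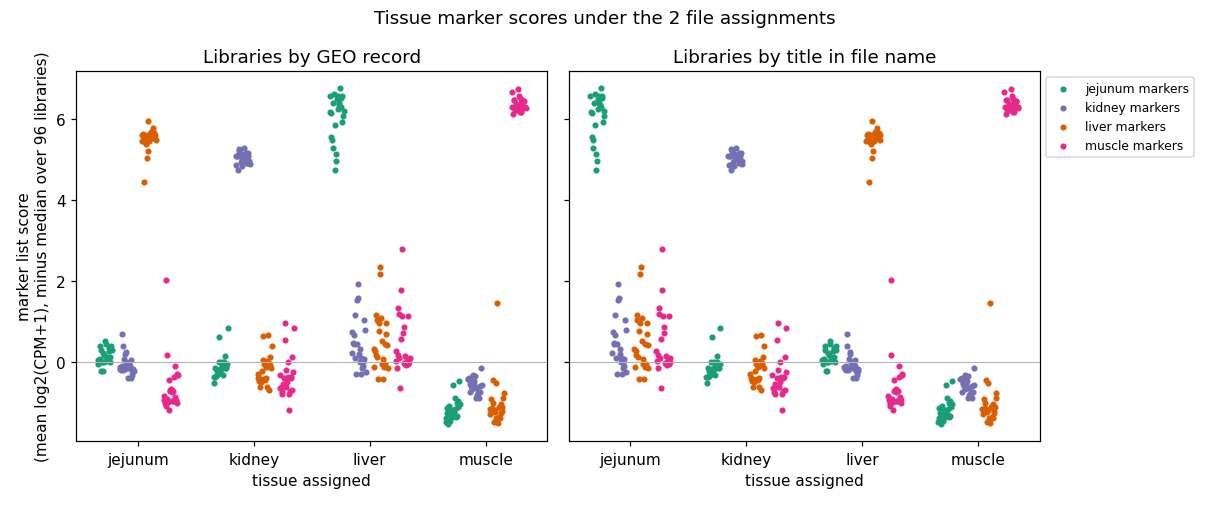
Scores of the 4 tissue marker lists (mean log2(CPM + 1) minus the median over 96 libraries) for each library, grouped by the recorded tissue on the left and by the tissue of the title in the file name on the right. Liver markers are highest in the 24 libraries recorded as jejunum and jejunum markers in the 24 recorded as liver, whereas all 96 libraries match their tissue by title.

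Under the record, the 24 libraries recorded as liver, which carried jejunum transcripts, differed most between diets. In them 1103 genes were higher and 1354 lower in xylose libraries, of 8477 tested. DCXR (ENSSSCG00000039873), the L-xylulose reductase of pentose metabolism, fell from 40.7 ± 23.6 to 10.4 ± 3.41 CPM (log2 fold change -1.90 ± 0.27, SE, adjusted p = 2.81e-05, n = 12 per diet). SORD (ENSSSCG00000004679), sorbitol dehydrogenase, which also oxidises xylitol, rose from 319 ± 105 to 466 ± 121 CPM (adjusted p = 0.0244). XYLB (ENSSSCG00000011254), the xylulose kinase, stood at 91.8 ± 40.6 and 91.1 ± 40.4 CPM (adjusted p = 0.963), and AKR1B1 was too low to be tested. Among genes with a symbol, NDRG1, TRIM23 and MSMO1 had the smallest p of those that rose (log2 fold changes 1.23, 0.90 and 1.26). SLC16A4, MLKL and LARP7 led those that fell (log2 fold changes -2.55, -2.99 and -2.05).

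Counts of list members in these libraries stand beside 2457 of all 8477 tested genes past the threshold, 1103 higher and 1354 lower. Among the fixed lists, intestinal digestion and nutrient absorption was higher, with 6 of 21 tested members past the threshold, or 8 when adjusted over the list alone. Its risen members included the disaccharidase SI (348 ± 280 to 807 ± 409 CPM) and the glucose transporter SLC2A2 (log2 fold change 0.84). Enterocyte markers rose in 4 of 17 members, respiratory chain genes in 9 of 36 and ribosomal protein genes in 8 of 33, or in 3, 7 and 0 when adjusted over the list alone. These 4 lists passed camera with adjusted p of 0.00086, 0.00873, 0.000247 and 0.000247, and none did with an estimated correlation (adjusted p = 0.852 for each). Skeletal muscle markers fell in 9 of 11 members (10 when adjusted over the list alone), and acute phase genes fell in 7 of 13, among them CRP (log2 fold change -2.80), and rose in 1 (9 passed when adjusted over the list alone). Camera gave adjusted p of 0.0153 and 0.0341 for the pair (0.852 with an estimated correlation). Liver hepatocyte markers fell in 4 of 15 members and kidney tubule markers in 5 of 6, as many as when adjusted over the list alone, and neither list passed camera (adjusted p = 0.0793 and 0.0739). The mitochondrial share of counts was 16.2 ± 9.32% in the control libraries, which are row A of the plate, and 7.02 ± 1.49% in the xylose libraries, which are row E. Without the 5 libraries under 1000000 counts, 962 genes passed, 267 higher and 695 lower. The skeletal muscle, enterocyte and ribosomal lists then no longer passed (camera adjusted p = 0.438, 0.0663 and 0.0692). The median log2 fold change of the hepatocyte list was then 0.02 in place of -0.78, and that of the tubule list -0.61 in place of -1.39.

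Muscle was the other tissue with many calls under the record. There 228 genes were higher and 64 lower in xylose libraries, of 8436 tested. RBP2, MYO1A and GAB2 led the risen genes (log2 fold changes 1.41, 1.01 and 1.39), and LAMP2, KLHL24 and MIB2 the fallen ones (-0.59, -0.76 and -0.73). Jejunum enterocyte markers, at low levels in muscle, rose in 6 of 9 members (7 when adjusted over the list alone), with RBP2 going from 3.65 ± 1.28 to 9.89 ± 3.53 CPM (camera adjusted p = 1.88e-06, and 0.784 with an estimated correlation). Abundant jejunum markers (10 genes) stood in muscle at 0.22% to 0.34% of their jejunum level, as reads misassigned from jejunum libraries would. Whether the enterocyte markers rose through such reads was not tested. Interferon genes fell in 2 of 27 members, IFI44L and IFIT1 (log2 fold changes -0.98 and -1.05), or in 8 when adjusted over the list alone (camera adjusted p = 0.00011, and 0.784 with an estimated correlation). The absorption list rose in 3 of 11 members, or 5 when adjusted over the list alone (camera adjusted p = 0.00661, and 0.784 with an estimated correlation). SLC2A4, the insulin-responsive glucose transporter, rose from 77.5 ± 16.8 to 107 ± 23.5 CPM. DESeq2 called 642 genes in place of 292.

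In kidney, 2 of 10128 genes passed under the record. CRP, the acute phase protein, fell from 22.4 ± 15.0 to 5.11 ± 2.07 CPM (log2 fold change -2.13 ± 0.28, adjusted p = 0.000367), and ENSSSCG00000002623 rose (1.08 ± 0.18, adjusted p = 0.00967). CRP was also lower, without passing, in the libraries with liver transcripts. Whether kidney reads of CRP came from other libraries was not tested. XYLB had a log2 fold change of -0.77 ± 0.19 (adjusted p = 0.297). DESeq2 called 32 genes. Acute phase genes were lower as a list, with 5 of 14 members when adjusted over the list alone and 1 over all genes (camera adjusted p = 0.00818, and 0.758 with an estimated correlation). Respiratory chain genes were higher (30 of 36 positive, camera adjusted p = 0.000759) and cholesterol synthesis genes lower (3 of 20 positive, 0.0489), each at 0.758 with an estimated correlation.

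In the libraries recorded as jejunum, which carried liver transcripts, edgeR called 0 of 9070 genes, with 672 at an unadjusted p under 0.05, 2 by DESeq2 and 46 by limma with library weights. The smallest p belonged to TCAP, MFGE8 and ANKRD1 above 0 (log2 fold changes 1.25, 0.89 and 1.13) and to B3GNT5, CRP and ENSSSCG00000013370 below it (-1.05, -2.16 and -4.22), none of which passed. Interferon genes were lower as a list in these libraries and in the kidney (camera adjusted p = 3.5e-07 and 0.0336), with adjusted p of 0.403 and 0.758 with an estimated correlation. Extracellular matrix genes, 10 of 10 positive, were higher in the libraries recorded as jejunum (camera adjusted p = 0.00125, and 0.302 with an estimated correlation). They were 1 of 8 lists that passed there, of which 6 were higher and 2 lower. Because diet followed lane and plate row throughout the record, none of these differences can be assigned to diet rather than to lane or row.

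By title, where each library carried its tissue's markers, no gene passed the threshold in any tissue with edgeR. Of 8477 genes in jejunum, 10128 in kidney, 9070 in liver and 8436 in muscle, 271, 773, 580 and 654 had an unadjusted p under 0.05. The smallest adjusted p were 1, 0.597, 0.743 and 0.366. DESeq2 and limma with library weights called 0 genes in the first 3 tissues. In muscle, DESeq2 called TMEM109 (log2 fold change -0.48), and limma called TMEM109, IGDCC4 and CNN1 (-0.51, 0.84 and -0.87). The 95% interval of the log2 fold change lay between -1 and 1 for 89.2% of genes in jejunum, 86.5% in kidney, 92.5% in liver and 91.7% in muscle. For each of those genes taken singly, a 2-fold change lay outside the interval. The intervals were not adjusted over genes, so some can miss the true value, and 2-fold changes are not excluded for all of them together.

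**Figure D3:**
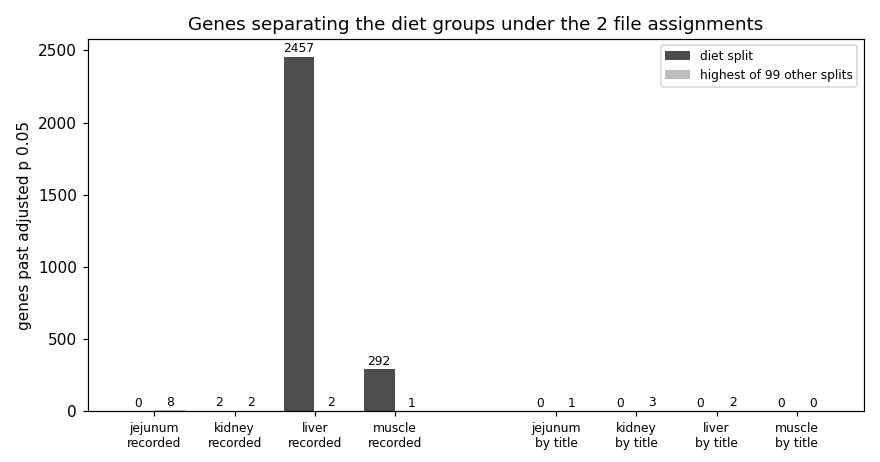
Genes past an adjusted p of 0.05 between diet groups (dark bars) per tissue, for the recorded files on the left and the files by title on the right, beside the highest count in 99 other splits of the same libraries (light bars). The record gives 2457 genes for libraries recorded as liver and 292 for muscle, and the titles give 0 in each tissue.

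No diet difference passed the threshold by title in the enzymes through which D-xylose can be metabolised. In liver, SORD stood at 1676 ± 199 CPM in control and 1546 ± 335 CPM in xylose libraries (log2 fold change -0.11 ± 0.14, adjusted p = 0.877, n = 12 per diet). DCXR stood at 15.3 ± 5.28 and 16.5 ± 8.97 CPM, XYLB at 83.9 ± 42.4 and 71.0 ± 34.9 CPM, and AKR1B1 (ENSSSCG00000040608), an aldose reductase, at 5.82 ± 3.24 and 5.71 ± 6.02 CPM. In kidney, SORD stood at 781 ± 208 and 738 ± 185 CPM, XYLB at 118 ± 42.9 and 109 ± 53.9 CPM, DCXR at 31.8 ± 11.7 and 33.4 ± 27.8 CPM and AKR1B1 at 17.8 ± 12.8 and 13.2 ± 6.69 CPM. In jejunum, XYLB stood at 106 ± 40.3 and 76.5 ± 34.0 CPM (log2 fold change -0.48 ± 0.22, unadjusted p = 0.041, adjusted p = 1), and SORD and DCXR had log2 fold changes of -0.02 ± 0.18 and 0.27 ± 0.27. In muscle, SORD had a log2 fold change of 0.61 ± 0.28 and DCXR of 0.73 ± 0.35 (adjusted p = 0.593 and 0.639), and AKR1B1 of -0.27 ± 0.17. The SD of SORD in the muscle xylose libraries, 40.3 CPM around a mean of 35.3 CPM, was above the mean, and without xylose replicate 7 its log2 fold change was 0.15. AKR1B1 in jejunum and XYLB in muscle were too low to be tested.

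**Figure D4:**
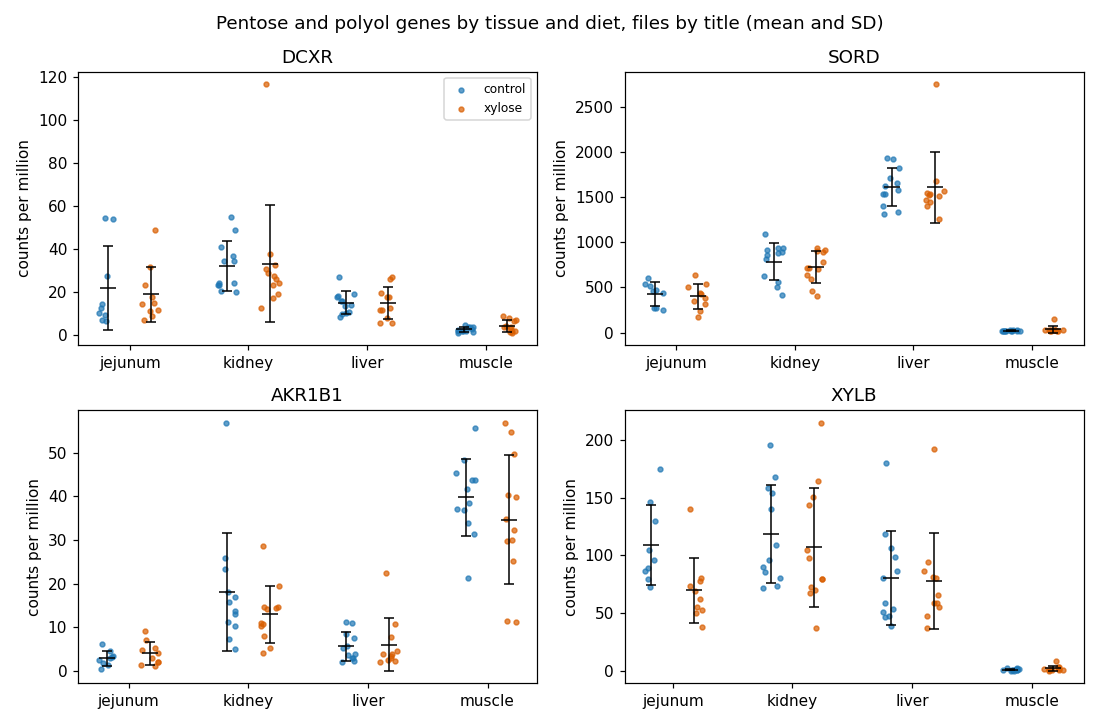
CPM of DCXR, SORD, AKR1B1 and XYLB per library by tissue and diet, files by title, without the 6 libraries under 1000000 counts, with mean and SD. The diets overlap in every tissue, while SORD is highest in liver and AKR1B1 in muscle.

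Cholesterol synthesis genes, targets of the transcription factor SREBP2, passed camera in both jejunum and liver by title, in opposite directions. In jejunum 18 of 20 tested members had positive log2 fold changes (median 0.24, camera adjusted p = 0.000433), and in liver 2 of 21 did (median -0.39, adjusted p = 0.000264). With an estimated correlation the adjusted p were 0.817 and 0.565, and no member passed by itself or when adjusted over the list alone. In liver the mean score of the list was lower on xylose by 0.53 on the log2 scale, and by 0.28 without the library of 13418 counts, xylose replicate 3. That library scored -2.78, and the next lowest liver score, -1.11, was that of xylose replicate 7, which had 6641726 counts. The difference without replicate 7 was not computed. Mean list scores of libraries were also compared by a permutation of diets within lanes. No list passed that test in any tissue by title (smallest adjusted p = 0.503 over 134 list tests), those called by camera included. FDFT1, squalene synthase, stood at 129 ± 34.7 and 198 ± 80.5 CPM in jejunum and at 478 ± 156 and 296 ± 145 CPM in liver. In jejunum, liver hepatocyte markers were also higher as a list (15 of 15 members positive, camera adjusted p = 0.0381, and 0.905 with an estimated correlation). Without the 5 jejunum libraries under 1000000 counts, the hepatocyte list had the smallest camera p (adjusted p = 0.000338), ahead of cholesterol synthesis (0.000976), and kidney tubule markers were higher too (0.00665), each at 0.859 with an estimated correlation. The genes with the smallest p in jejunum were TTLL12, ENSSSCG00000039658 and ENSSSCG00000004024 above 0 (log2 fold changes 0.76, 0.71 and 0.66) and ATP7B, SAAL1 and SFXN1 below it (-0.64, -0.60 and -0.53), none of which passed.

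In liver by title, macrophage markers were lower as a list, with 0 of 9 members positive and CD14 at 543 ± 165 and 417 ± 111 CPM (camera adjusted p = 0.00568, and 0.565 with an estimated correlation). Ribosomal protein genes had 7 of 32 members positive (camera adjusted p = 0.0191, and 0.678 with an estimated correlation). Without the library of 13418 counts, xylose replicate 3, the ribosomal list no longer passed (camera adjusted p = 0.228), the macrophage and cholesterol lists did (0.0154 and 0.00161), and T and NK cell markers were lower as a list (0.022), each of the last 3 at 0.567 with an estimated correlation. ERG28, a protein of sterol synthesis, had the smallest unadjusted p below 0, at 545 ± 182 and 304 ± 93.6 CPM (log2 fold change -0.82 ± 0.18, adjusted p = 0.743). LRATD1 and VAC14 followed (-1.08 and -0.79), and ENSSSCG00000039935, XIAP and TEX30 led above 0 (0.76, 0.64 and 0.84). None of these 6 passed.

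In kidney by title, 3 of 19 pentose, polyol and glucuronate genes had positive log2 fold changes (median -0.14, camera adjusted p = 0.0225, and 0.526 with an estimated correlation). Among them AKR1A1, an aldehyde reductase, stood at 409 ± 99.5 and 309 ± 87.4 CPM and TKT, the transketolase of the pentose phosphate pathway, at 195 ± 67.9 and 144 ± 41.6 CPM, and no member passed by itself. Monosaccharide transporters were not called as a list in any tissue by title (camera adjusted p = 0.712 in jejunum, 0.491 in kidney, 0.754 in liver and 0.991 in muscle). Interferon genes were higher as a list in kidney (23 of 28 positive, camera adjusted p = 0.00978, and 0.63 with an estimated correlation), as were acute phase genes (12 of 14, 0.00978, and 0.59 with an estimated correlation). The permutation of diets over libraries gave unadjusted p of 0.2 and 0.074 for the mean scores of these lists. Skeletal muscle and liver markers were higher in the same xylose kidney libraries (10 of 11 and 13 of 16 positive, camera adjusted p = 0.00948 and 0.0225, and 0.63 for each with an estimated correlation). The mitochondrial share of counts was 7.89 ± 1.88% in the control and 10.6 ± 3.66% in the xylose kidney libraries. Xylose replicates 5 and 12 had the highest share of other tissues' markers in kidney (1.23% and 1.05% of counts), with mitochondrial shares of 18.9% and 12.0%. ZCCHC17, SOS2 and ENSSSCG00000018061 had the smallest unadjusted p above 0 (log2 fold changes 0.53 and 0.59 for the first pair, and 2338 ± 836 and 4684 ± 3263 CPM for the last) and SAL1, ASIC1 and BRAT1 below it (-3.79, -1.20 and -0.97), none of which passed.

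In muscle by title, NRF2 targets of the oxidative stress response were higher as a list (10 of 11 positive, camera adjusted p = 0.0132, and 0.133 with an estimated correlation), with ME1 at 19.7 ± 6.53 and 28.9 ± 9.47 CPM and TXNRD1 at 27.4 ± 7.42 and 36.0 ± 11.0 CPM. Endothelial and smooth muscle markers were lower (0 of 7 and 1 of 5 positive, camera adjusted p = 0.0365 for each, and 0.39 with an estimated correlation), as were ribosomal protein genes (6 of 33, 0.00726, and 0.435 with an estimated correlation). Liver hepatocyte markers were higher, 13 of 14 when adjusted over the list alone and 0 over all genes (camera adjusted p = 3.51e-07, and 0.39 with an estimated correlation). Absorption, enterocyte and bile acid lists were also higher (camera adjusted p = 0.00216, 0.0177 and 0.0365, and 0.39, 0.435 and 0.39 with an estimated correlation). The muscle library of xylose replicate 7 carried more liver transcripts than the other muscle libraries, with a liver marker score of 1.45. Without it the liver list had a median log2 fold change of 0.31 in place of 0.94, and 3 lists passed in place of 8. These were the hepatocyte, NRF2 and smooth muscle lists (camera adjusted p = 0.000456, 0.0253 and 0.0253, and 0.68, 0.219 and 0.582 with an estimated correlation). The endothelial, ribosomal, absorption, enterocyte and bile acid lists no longer passed (camera adjusted p = 0.0906, 0.0766, 0.0766, 0.137 and 0.349). LRTM1, IGDCC4 and ENSSSCG00000010401 had the smallest unadjusted p above 0 (log2 fold changes 1.11, 0.72 and 0.58), and TMEM109, THAP3 and CASTOR1 below it (-0.49, -0.76 and -0.65), none of which passed.

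Whether the diet effect differed between tissues was tested over all 96 libraries. Under the record it differed for 1955 of 12119 genes, and by title for 2, GJB1, a gap junction protein of hepatocytes (adjusted p = 0.0111), and AMDHD1, an enzyme of histidine breakdown in liver (adjusted p = 0.0286). In muscle, GJB1 stood at 3.32 ± 0.85 CPM in control and 26.2 ± 75.5 CPM in xylose libraries. Without the muscle library with liver transcripts, 0 genes passed by title and 543 had an unadjusted p under 0.05. With the plate position as a replicate block 0 passed as well, with 442 at an unadjusted p under 0.05.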

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

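The library depth, mitochondrial share and recorded diet tests below were set before their results were seen, and the lane test and the cholesterol test after.

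The diet effect differed between tissues for 1955 genes under the record and for 2 genes by title. Under the record, 1 of 100 splits of the 24 animals gave as many genes, the highest other split giving 202, so chance can be excluded. By title, 23 of 100 splits did, the highest other giving 24, so chance cannot be excluded. A split with several times the real count points to a structure of the samples, for which an outlying library would be enough, and this was not tested. The 2 calls by title ended with the plate position as a replicate block (0 genes by edgeR, 442 at an unadjusted p under 0.05) and without the muscle library with liver transcripts (0 genes, 543).

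The 1955 genes lie beside 2457 that separated plate rows A and E in the libraries with jejunum transcripts, where 1 of 100 splits gave as many (highest other 2). A lane effect of this size shared by all tissues is argued against, since the same lanes gave 0 genes in the libraries with liver transcripts (672 at an unadjusted p under 0.05, 46 by limma with weights, 2 by DESeq2), but smaller shared effects remain open, with 2 genes in kidney, 292 in muscle, and CRP called lower in lane 8 in kidney as well as in the libraries with jejunum transcripts. Library depth remains open, since 962 genes passed without the 5 shallow libraries (4 of row A and 1 of row E), while 20 random removals of as many other libraries left 911 to 3855 with a median of 2801. The mitochondrial RNA share also remains open, since 347 genes passed with it as a covariate, although the share itself follows the row. Diet as recorded cannot be told apart from row and lane, since 0 row A libraries are recorded as xylose.

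The cholesterol synthesis list differed between jejunum and liver in its diet effect by title, by 0.75 on the log2 scale (xylose minus control, jejunum minus liver). A permutation of diets within lanes gave p = 0.00947 for this difference, which does not test that the signs are opposite. For the difference, here and without the shallow libraries, diets were permuted independently in the 2 tissues. Any sharing of animals between the tissues was therefore ignored. Without the libraries under 1000000 counts, the difference was 0.50 (permutation p = 0.0221). The effect was then 0.22 within jejunum (permutation p = 0.0396) and -0.28 within liver (permutation p = 0.152, without xylose replicate 3). With all libraries the effect within jejunum was 0.23 (permutation p = 0.05) and within liver -0.53 (permutation p = 0.0719), and the adjusted p over 134 list tests was 0.503 for each. The list was chosen because its camera calls already went in opposite directions, so the difference may rest on that choice, and an opposite diet response in the 2 tissues is a hypothesis that these values do not settle.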

How the results depend on the processing

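The fits without libraries were chosen after seeing the data, and the other alternatives before. By title the count of 0 genes held in jejunum and liver under each alternative that kept the assignment. It became 1 in kidney without a count filter (ENSSSCG00000039377), and in muscle 1 with DESeq2 (TMEM109), 3 with limma weights (TMEM109, IGDCC4 and CNN1) and 1 without the library with liver transcripts (CNN1). With the recorded files it was 2 in kidney, 2457 in liver and 292 in muscle, in place of 0, and the titles gave 0 in place of each of these. Under the record, the 0 genes for jejunum became 1 with DESeq2 size factors, 1 with the 1 CPM filter, 1 with the older edgeR fit, 1 without the shallow library (TCAP each time), 2 with DESeq2, 7 without a filter and 46 with limma weights. The 2 in kidney became 4 without a filter, 4 with the 1 CPM filter, 16 with limma weights and 32 with DESeq2. The 2457 for liver became 962 without the shallow libraries, and the 292 in muscle 642 with DESeq2. Every gene list call was lost with an estimated correlation (0 lists in each tissue under both assignments, and a smallest adjusted p of 0.219 in the fits without libraries). Without the doubted libraries the lists under the record numbered 5 for jejunum, 3 for liver and 5 for muscle, and by title 3 in jejunum in place of 2, 3 in liver (2 of them shared with the 3 of all libraries) and 3 in muscle in place of 8. The cause was not tested for these changes. Fewer libraries or genes entered some fits, and the 2 assignments compared different libraries or different splits of the same ones.

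As to pairing, the labels do not say which samples share an animal. Deviations at the same plate position correlated across genes with a mean r of 0.066 to 0.129 between tissues, the lowest was -0.262, and 4 to 7 of 24 libraries correlated best with their own position. The replicate block with the plate position as animal gave 0 genes whose diet effect differs between tissues by title, in place of 2, and 2582 under the record, in place of 1955. By title 0 also passed without the library with liver transcripts.

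Among genes chosen by the naming rule and called under 1 assignment, the log2 fold changes that turned sign did so between assignments. The 2 assignments compare different things, so a turned sign does not show an unstable diet effect. For liver they share no library. In kidney and muscle they split the same libraries, by lane under the record and within lanes by title. Other called genes were not examined for sign changes. By title the following values of these chosen genes replaced called ones of the opposite sign. In kidney it was CRP 0.445. In liver, where the record holds jejunum transcripts and the titles liver transcripts, they were SORD -0.106, NDRG1 -0.291, MSMO1 -0.213, SLC16A4 0.229, CPS1 0.437, FGB 0.238, FGG 0.394, MYL1 0.18, PGAM2 0.065, DEFB1 0.211, CD3D -0.536, C1QC -0.329, C1QA -0.323, GATA3 0.052, MLXIPL 0.032, SLC25A20 -0.021, PDIA3 0.096, GBP2 0.286, CRP 0.523, ITIH4 0.337, CIART 0.027, IER3 0.24, RPS23 -0.335, RPL4 -0.048, SLC38A2 -0.076. In muscle they were SLC2A4 -0.109, IDI1 0.449, IFI44L 0.156, NDUFA5 -0.085, NDUFB9 -0.05, AQP1 -0.276. With the recorded files, SORD in liver was 0.544 in place of -0.106. Simulated recovery of 1.5-fold changes was 10.9% in jejunum and 26.9% in muscle, and how much of this comes from depth was not tested.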

Other observations

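The misassignment, background, plate position and averaged diet tests were set before their results were seen, and the interferon test and the tissue levels of sugar genes were chosen after.

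Genes of pentose, polyol and glucuronate metabolism and of sugar transport were distributed unevenly over the 4 tissues by title. Levels are over libraries of 1000000 counts or more (19 jejunum, 24 kidney, 23 liver and 24 muscle). SLC5A1, the intestinal sodium-glucose cotransporter, stood at 2095 ± 845 CPM in jejunum (SD) and at 28.9 ± 12.7 CPM in kidney. XYLB stood at 88.3 ± 36.3 CPM in jejunum, 113 ± 46.4 in kidney and 79.4 ± 40.3 in liver, against 1.76 ± 1.70 CPM in muscle. DCXR was 20.1 ± 15.9, 32.4 ± 20.5, 14.7 ± 6.25 and 3.27 ± 2.20 CPM in the same order. SORD was highest in liver, at 1609 ± 303 CPM, and AKR1B1 in muscle, at 37.2 ± 12.2 CPM. In kidney, CRYL1, which oxidises L-gulonate toward L-xylulose, reached 1633 ± 619 CPM, and MIOX, which forms glucuronate from inositol, 2127 ± 359 CPM. The fructose transporter SLC2A5 stood at 82.5 ± 38.1 CPM in jejunum and 0.50 ± 0.42 CPM in liver. Each of these genes differed between tissues by edgeR (adjusted p from 6.81e-64 for SLC5A1 to 1.33e-09 for DCXR). That fit used all 96 libraries, the shallow ones included, with a lane term and no animal term.

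Libraries at the same plate position in the 4 tissues resembled each other in a set of genes. With 50 genes chosen in 3 tissues, at least 17 of 24 libraries of the held-out tissue matched their own position best, 19 in jejunum, 17 in kidney, 22 in liver and 19 in muscle. Leading genes included ND2, NDUFA10, TUFM and ECHDC1. A plate column effect common to both lanes is argued against, since the mean correlation with the same column in the other lane was 0.04. A column effect within a lane could not be told apart from position by this test. The result fits a shared animal, and the genes may differ by inherited variants, which were not tested. The record links the same 4 libraries for all 24 animals and gives the same lowest count, 17, so animals linked by the recorded files fit as well. This check therefore does not choose between the assignments.

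Interferon genes varied together across tissues of a position, over 22 genes expressed in all tissues and 24 positions, centred within tissue and lane. Spearman's rho was above 0.4 in 4 of 6 pairs of tissues. Kidney and liver gave rho 0.74 (permutation p = 6e-05, adjusted 0.00036) and Pearson's r 0.55 (permutation p = 0.00286), and r 0.52 without the 2 positions farthest from the median. Liver and muscle gave rho 0.59 (p = 0.00278) and r 0.51 (p = 0.0101), and r 0.66 without 2 positions, and kidney and muscle rho 0.53 (p = 0.00827) and r 0.60 (p = 0.00228), and r 0.53 without 2. The adjusted p of rho were 0.00834 and 0.0165 by permutation. Jejunum gave rho 0.43 with liver (permutation p = 0.0378, adjusted 0.0567), 0.32 with muscle and 0.22 with kidney. Without the 2 farthest positions the rho of jejunum and liver was 0.38, no longer above 0.4. Animal-wide interferon activity is a candidate explanation, and the 4 pairs were found and tested on the same data.

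Transcripts of other tissues were present in the libraries. Over markers of 500 CPM or more in their source, muscle markers stood at a median of 1.15% of their muscle level in jejunum, 0.77% in kidney and 0.57% in liver. Over the 12 pairs of tissues the median SD of the log2 fraction over genes was 0.30, which fits reads misassigned between libraries, though not in every pair. The SD was 1.5 and 1.93 for jejunum markers in kidney and liver, and 1.6 for kidney markers in liver. In these pairs the median fraction was 0.58%, 0.37% and 0.47%. The medians were nearer the lowest fraction (0.34%, 0.24% and 0.42%) than the highest (11.2%, 11.4% and 5.6%). The spread there thus lay in markers above the median, and whether the target tissue expresses those itself was not tested. For liver markers the SD was 1.12 in jejunum and 0.82 in kidney. A fixed background per library remains open. The share of such transcripts fell with library total within lanes, with Spearman's rho -0.79 in lane 7 (permutation p = 1e-05, the smallest possible) and -0.41 in lane 8 (p = 0.00444) over 48 libraries each. Pearson's r was -0.89 and -0.51, and -0.80 and -0.43 without the 2 libraries farthest from the median.

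A small diet effect shared by tissues was sought by title as the mean over the 4 tissues with the animal as a random effect in limma. It passed in 0 of 12119 genes, with 596 at an unadjusted p under 0.05 and a smallest adjusted p of 0.938.

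Chance was tested for the other counts with 100 splits of the 24 libraries of a tissue, within lanes by title. Under the record, 1 split gave as many genes as the 292 in muscle (highest other 1), so chance can be excluded there. In kidney, 3 splits gave as many as the 2 genes (highest other 2). Other splits thus reached the real count, and chance cannot be excluded for it. For gene lists under the record, 16 splits gave as many as the 8 lists for jejunum (highest other 15), 36 as many as the 4 for kidney (highest other 9), 53 as many as the 6 for liver (highest other 14) and 71 as many as the 3 for muscle (highest other 12). Where the real count was 0 genes, in each tissue by title and for libraries recorded as jejunum, all 100 splits reach it by construction and say nothing about chance (highest other 1 in jejunum, 3 in kidney, 2 in liver and 0 in muscle by title, and 8 under the record). For gene lists by title, 88 splits gave as many as the 2 in jejunum (highest other 17), 25 as many as the 5 in kidney (highest other 10), 73 as many as the 3 in liver (highest other 14) and 21 as many as the 8 in muscle (highest other 11). Chance cannot be excluded for any of the list counts.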
